A study of Mus musculus with 4 samples.

How the data were processed

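Each of the 4 samples was a single-cell library made with 10x 5' kit version 2 and feature barcodes for cell surface protein, per the labels' protocols. The count matrices were deposited as UMI counts per gene and barcode, whole numbers with no normalization. Cell Ranger and build mm10 are named in the submitters' processing notes; the software version is not given in the sources used here. Each filtered matrix also holds counts of 2 sample tags, which the authors deposited as features named mHTO01 and mHTO02. Filtered matrices of 3 libraries were analysed, with an unfiltered matrix for Smarta CD4 replicate 2. For CD11b replicate 2 only the barcode list was used here. Features were 32285 genes, of which 38 symbols have 2 identifiers; symbols and identifiers are those of the files. Coordinates are from GENCODE M21 on the same build, counted from 1.

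Groups and replicate numbers follow the sample titles. Libraries had 52929390, 93041713 and 55595722 gene UMIs. Cells were kept with at least 500 genes and under 10% mitochondrial UMIs, which left 6287, 10569 and 10258. The doublet caller (scrublet within scanpy 1.11.5, seed 7) marked 0, 2 and 0 cells, so few that it has not worked. Cells with both tags, 2.75, 2.88 and 4.65% of the libraries, were used in its place in an added alternative. Such cells can show only pairs with unlike tags, so pairs of cells with the same tag were not detected. A tag was assigned at 50 or more tag UMIs and 4 times the other tag. Each cell's UMIs were split at random with a share of 0.5. Clusters (Leiden in igraph 0.11.9, resolution 1, 30 principal components, 2000 variable genes, 15 neighbors) were made from one part without the genes of the test lists, and levels came from the other part. The comparison of the T cell with the CD11b library used all UMIs of the kept cells, without T cell-like and non-immune clusters.

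Clusters were named from 29 marker lists, and 19 test lists of 260 genes, of which 259 were found, were compared. Lists, filters, resolution and comparisons were fixed before the data were examined. A marker counted at 1.5 times the level in the other cells, with a UMI in at least 10% of the cluster's cells, and a name needed at least 3. A cluster stayed unnamed when its 10 leading genes held more markers of another class, when its median UMIs were over 3 times under the library's with no marker leading, when over 2 times the library's share of its cells carried both tags, or when Ptprc was over 4 times under the library's level. These thresholds and the last conditions were set after clusters had been seen, and 4 versions of the naming rule were tried: an exploratory listing, the both-tags condition, the leading-genes condition, and both together. The both-tags condition kept clusters 9 and 10 of Smarta CD4 replicate 2 (2.02% and 7.37%) and clusters 2, 3 and 10 of CD11b replicate 1 (10.1%, 10.5% and 2.00%) out of a class. In the library labelled Smarta CD4 replicate 1 it kept out cluster 6 (5.58%). The leading-genes condition kept out cluster 4 (10.4%) and low depth cluster 1 (5.44%) of Smarta CD4 replicate 2.

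Raw counts were summed per class and scaled to a common total (CPM) with exact Poisson intervals; ratios have exact intervals from the binomial share of 2 counts. A class with 0 UMIs entered a ratio at a floor of 3 UMIs. With 1 library per comparison there was no test. A list member was called higher or lower at 50 CPM or more in either class, a ratio of at least 2 and intervals that did not overlap. Genes named were the 3 members of each list with the largest ratio among those called, with Rag1, Cd4, Cd3e, Itgam, Ptprc and Klrb1c as label checks; Lyz2, Trac, Trbv13-1, Csf1r and Cd8a were added after the first values were seen. The planned rule for replicated tests, the 10 largest changes each way with an adjusted p under 0.05, could not be used. Not every gene that the rule names is reported here. A list's median log2 ratio (CPM + 5, members at a mean of 5 CPM or more) was placed among 10000 random lists matched in 20 expression bins. Genes of a random list were drawn separately, so correlation among the genes of a real list is not covered. The random ranges may therefore be too narrow, and the percentiles are not calibrated p-values. UMIs are molecules, but intervals cover counting error only, not differences between animals; the labels do not say that replicate libraries came from separate mice.

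Tests of T cell classes across both Smarta libraries, planned with edgeR and camera, were not run, since the library labelled Smarta CD4 replicate 1 has no T cell class. The test with groups as labelled used edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 in R 4.3.3 on deposited counts. On simulated data the ratio rule recovered 50 of 50 genes planted at 3-fold and 47 of 50 at 0.333-fold in the T cell contrast, with 0 calls among 2701 unchanged genes. In the macrophage contrast it recovered 50 and 49 of 50, with 0 calls among 2554; genes at 1.5-fold were recovered in 0 of 50 in each. Of 40 unchanged lists, 0 and 1 fell outside the range of random lists in these contrasts. These simulated counts held Poisson error only, with no variation between cells or animals and no correlation among genes. They check the arithmetic of the rule and give no false-call rate for the real data. Genes at 1.5-fold lie under the ratio of at least 2 that the rule needs. The edgeR step, run on 32285 genes for 2 libraries against 1, recovered 199 of 200 genes planted at 8-fold at a dispersion of 0.05, with 9 false calls. At the dispersion of the labelled libraries, 1.14, it recovered 0 of 200, so the 0 calls with groups as labelled do not bear on whether any gene differs. Alternatives numbered 55 planned and 19 added after seeing the data: the both-tags, single-tag, naming, comparison-class, depth, doublet and list settings that sensitivity values name. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and Python 3.11.15.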

Results

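The series profiled immune cells of C10 tumors in Rag1-deficient mice, which make no T or B cells of their own. Mice were given vehicle or Smarta cells, CD4 T cells with a transgenic receptor, on day 4, and cells were collected on day 10. The labels name 2 groups of 2 libraries each: Smarta CD4 T cells pooled from draining lymph node and tumor, and CD45-positive, CD11b-positive, NK1.1-negative cells from tumors of mice given vehicle or Smarta cells. Transcripts were counted as unique molecular identifiers (UMIs) with 5' chemistry, and levels are UMIs scaled to a common total (CPM). The library labelled Smarta CD4 replicate 1 held 6621 cell barcodes with 52929390 gene UMIs, Smarta CD4 replicate 2 held 10725 barcodes with 93041713, and CD11b replicate 1 held 11455 barcodes with 55595722. Median UMIs per barcode were 5980, 6893 and 3630. Of CD11b replicate 2 the barcode list was read, with 16542 barcodes, and its counts were not analysed here. Intervals throughout are exact 95% Poisson or binomial (Clopper-Pearson) intervals and cover counting error only.

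T cell transcripts were present in only 1 of the libraries labelled Smarta CD4. In Smarta CD4 replicate 2, Cd3e, a chain of the T cell receptor complex, was at 653 CPM (647 to 658) and was detected in 94.0% of barcodes. Cd4 there was at 209 CPM (206 to 212), and Trbv13-1, the Smarta receptor's variable beta segment, was at 6094 CPM (6078 to 6109.6) with a UMI in 99.0% of barcodes. In the library labelled Smarta CD4 replicate 1, Cd3e had 1 UMI, which is 0.0189 CPM (0.000478 to 0.105). Cd4 was at 0.0756 CPM (0.0206 to 0.193) and Trbv13-1 had 0 UMIs in 6621 barcodes, with an interval up to 0.0697 CPM. That library instead carried Lyz2, the myeloid lysozyme gene, at 5514 CPM (5494 to 5534), and Itgam, which encodes CD11b, at 351 CPM (346 to 357). CD11b replicate 1 had Lyz2 at 6490.3 CPM (6469 to 6511), Itgam at 360.2 CPM (355 to 365) and Cd3e at 1.91 CPM (1.56 to 2.31). In Smarta CD4 replicate 2 Lyz2 was at 1.33 CPM (1.11 to 1.59) and had a UMI in 0.196% of barcodes, at a median of 6893 UMIs. Ptprc, the CD45 gene, was at 609 CPM (602 to 615), 697 CPM (691 to 702) and 569.6 CPM (563 to 576) in the same order of libraries. Klrb1c, which encodes NK1.1, stayed below 1 CPM in each, and Rag1 had 0 UMIs in Smarta CD4 replicate 2 against 0.416 and 0.684 CPM in the others. The gene checked first, Cd3e (ENSMUSG00000032093, chromosome 9, 44998740 to 45009627), and Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321) are given in mm10 coordinates. The labels were not reassigned: the first library is called the library labelled Smarta CD4 replicate 1, and below it stands for T cells only where the groups are taken as labelled.

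**Figure D1:**
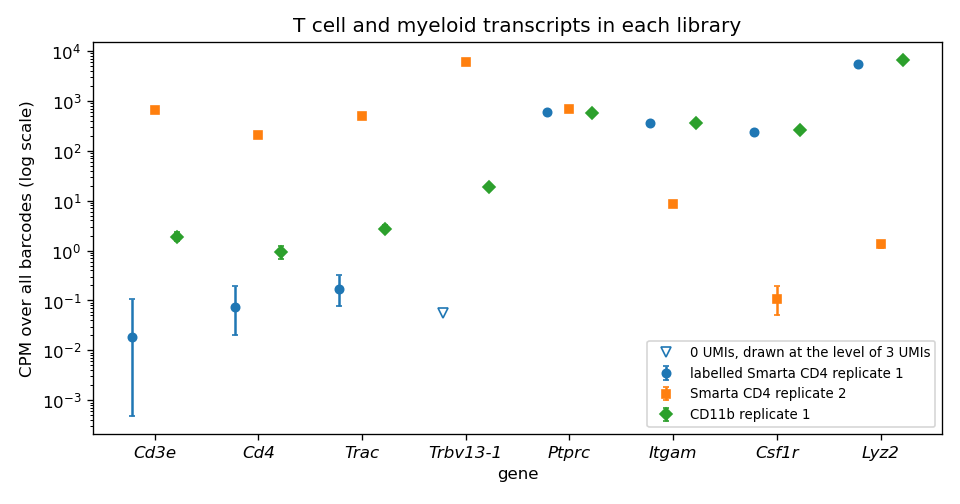
Level of 8 genes (CPM, log scale) over all barcodes of the 3 libraries; points are values, bars exact 95% Poisson intervals, and an open triangle marks 0 UMIs, drawn at the level of 3 UMIs. Cd3e, Cd4, Trac and Trbv13-1 lie under 1 CPM in the library labelled Smarta CD4 replicate 1, where Lyz2 reaches 5514 CPM.

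The states within the Smarta T cells were described in Smarta CD4 replicate 2, with 10569 cells after filtering. A Th1 effector-like class, led by Il2, Il3, Ccl4, Ccl3 and Ifng, made up 10.6% (10.0 to 11.2) of cells. Interferon-stimulated-like cells, led by Ifit3, Ifit1 and Slfn5 together with Tcf7, a transcription factor gene of naive and memory cells, made up 4.38% (4.00 to 4.79). Proliferating-like cells, led by Ube2c and Cenpf or by histone genes, made up 18.9% (18.2 to 19.7). Clusters that took no name held 66.1% (65.2 to 67.0) of cells. Among these, cluster 0 was led by Bbc3, Il7r and Txnip (16.9%), cluster 7 by Fabp5 and the replication genes Cdc6 and Hells (12.9%), and cluster 4 by Ccl5, Fos, Klrg1 and Cd69 (10.4%). No cluster was named memory or stem-like, regulatory, follicular helper, Th2, Th17 or cytotoxic in the main setting. A cytotoxic-like class appeared in 6 other settings, at 0.0852 to 12.2% of cells, and a memory or stem-like class in 4, at 5.75 to 27.4%. Lymph node and tumor cells were pooled in proportions not given in the sources used here, and with 1 library nothing was tested. At resolutions 0.5 and 2, with the test lists left in or with cells thinned to 2000 UMIs, no cluster took the name Th1 effector-like. Across settings interferon-stimulated-like cells ranged over 2.77 to 12.7% and proliferating-like cells over 18.0 to 48.8%.

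The planned contrast within T cells set Th1 effector-like against memory-like cells. With no memory-like cluster, the interferon-stimulated-like class, which carried 5 of the memory or stem markers, took that side. Of 17 cytokine genes 5 were higher and 1 lower in the 1121 Th1 effector-like cells against the 463 interferon-stimulated-like cells, and of 17 chemokine genes 4 were higher. Il2, the T cell growth factor, was at 4579.7 against 1.65 CPM, 2781-fold higher (95% interval 769.7 to 22961). Csf2, which encodes GM-CSF, was 264-fold (147 to 528) higher at 2387 against 9.06 CPM, and the inflammatory chemokine genes Ccl3 and Ccl4 were 878-fold (300.4 to 4258) and 6143-fold (1102 to 242646) higher. Il3 was at 1652 against 0.824 CPM and Ccl1 at 1313 against 0.824 CPM. Of the denominators, Il2 rested on 2 UMIs, Ccl3 on 3 and Il3, Ccl1 and Ccl4 on 1 each. The lower cytokine, named after its value was seen, was the lymphotoxin gene Ltb at 218 against 712 CPM. All listed genes were left out of the features that formed the clusters, and values came from UMIs not used for clustering.

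Receptors and transcription factors of recent activation were higher in the same cells. Among co-stimulatory receptors and ligands, 6 of 10 were higher, with Tnfrsf9 (4-1BB) 18.5-fold (14.7 to 23.6), Tnfrsf4 (OX40) 4.44-fold (4.04 to 4.90) and Tnfsf11 (RANKL) 3.79-fold (2.92 to 5.01). Of co-inhibitory receptors 3 of 10 were higher: Havcr2 (TIM-3) 14.5-fold (9.05 to 25.1), Lag3 11.3-fold (5.92 to 24.9) and Ctla4 6.87-fold (5.66 to 8.41). The NR4A, AP-1 and activation list had 11 of 24 higher and 1 lower, led by Nr4a1 14.5-fold (11.2 to 19.3), Nr4a3 13.9-fold (8.77 to 23.6) and Nr4a2 11.3-fold (6.67 to 20.7). Glycolysis genes were higher for 9 of 14 measured, with the lactate transporter Slc16a3 10.3-fold (6.01 to 19.5), Tpi1 5.29-fold (4.63 to 6.06) and the glucose transporter Slc2a1 3.85-fold (2.92 to 5.20). Hypoxia genes were higher for 6 of 10, with Bnip3 25.1-fold (9.73 to 92.3), Ndrg1 16.9-fold (8.52 to 39.3) and P4ha1 6.29-fold (3.56 to 12.3). The heat shock and dissociation stress list, a sign of handling as well as of activation, had 7 of 10 higher, with Hspa1a 9.63-fold (6.63 to 14.5), Hspa1b 8.82-fold (6.03 to 13.4) and Ier3 7.37-fold (4.57 to 12.7). The chemokine receptor gene Ccr8 was 124-fold (22.1 to 4888) higher, Rgs1 15.2-fold (11.3 to 20.9) and the retention marker Cd69 2.97-fold (2.52 to 3.52). Fasl was 4.16-fold (2.72 to 6.71) higher, Bcl2l1 3.44-fold (2.35 to 5.23), Pdcd1lg2 3.87-fold (2.47 to 6.41), Lgals3 2.24-fold (2.00 to 2.51) and Il10ra 2.29-fold (1.57 to 3.44).

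Few listed genes were lower in the Th1 effector-like cells. The lysosomal protease Ctss was 4.11-fold (3.34 to 5.05) lower, Cd74 2.54-fold (2.11 to 3.05), the integrin chain Itgb1 2.36-fold (2.20 to 2.53), the sphingosine phosphate receptor S1pr4 2.27-fold (1.99 to 2.59), the interferon-induced GTPase Irgm1 2.36-fold (1.99 to 2.79), Ifnar1 2.15-fold (1.60 to 2.86) and Il27ra 2.09-fold (1.68 to 2.59). Cd274 and Icam1, on the same interferon-gamma response list as Irgm1, were 2.63-fold (1.80 to 3.98) and 2.08-fold (1.59 to 2.79) higher. None of 16 oxidative phosphorylation genes, 16 cytosolic ribosomal protein genes or 9 MHC class I presentation genes met the rule. In all, 62 of 259 measured list members were higher and 10 lower at 50 CPM or more in either class, a ratio of at least 2 and intervals that did not overlap. The lower count fell to 5 without cells carrying both tags, where a memory-like class took the comparison side, and to 2 against all other T cells. With 1 library there was no test, and the comparison class had itself been named by interferon-stimulated genes.

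This contrast is also largely one between the sample tags, whose meaning is not given in the sources used here. The tag mHTO02 marked 98.9% of singly tagged Th1 effector-like cells and 21.7% of singly tagged interferon-stimulated-like cells. Among cells with mHTO02 alone, a setting added after seeing the data, 1057 cells stood against 99, and 48 list members were higher and 14 lower. There the log2 ratio of Il2 was 8.27 in place of 11.44, of Csf2 6.60 in place of 8.04, of Tnfrsf9 3.49 in place of 4.21 and of Nr4a1 1.77 in place of 3.86. Genes that no longer met the rule included Cd69 at -0.04, Hspa1a at 0.99, Hspa1b at 0.75, Il10ra at 0.34, Cd274 at 0.48, Icam1 at 0.22, Fasl at 1.09 and Cd74 at -0.66. Of these, Fasl kept a ratio over 2 and missed the rule's level or interval condition. The interferon-stimulated-like side held 195370 UMIs there against 1214268 in the main contrast, so some losses may reflect fewer counts. With 12 Th1 effector-like cells, under the least number set for a class, the contrast with mHTO01 alone was not run.

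Set against 10000 random lists matched on expression but not on correlation among genes, the median log2 ratio lay above the 95% range for 9 lists. It was 7.82 for chemokines (5 expressed members), 2.30 for cytokines, 2.17 for hypoxia, 1.66 for heat shock, 1.40 for NR4A and AP-1, 1.36 for co-stimulation, 1.35 for glycolysis, 1.21 for chemokine receptors and 0.93 for co-inhibition. It lay below that range for interferon-gamma response at -0.41 (percentile 0.170) and MHC class II presentation at -0.51 (percentile 1.47). The MHC class II median rested on 6 expressed members of 10, of which 2, Ctss and Cd74, met the rule. Medians within the range were -0.22 for cytokine receptors, -0.31 for adhesion, -0.36 for MHC class I, -0.12 for oxidative phosphorylation, 0.04 for lysosome and lipid handling, 0.29 for apoptosis regulators and -0.02 for ribosomal proteins. The immunosuppressive myeloid list had too few expressed members for a median. Against all other T cells the interferon-gamma response list turned, with a median of 0.44 above its range, and 3 of its 20 genes were higher. No list lay below the range there or with doublets kept, and 1 did with all UMIs. The leading genes are Il2 (ENSMUSG00000027720, chromosome 3, 37120523 to 37125959), Csf2 (ENSMUSG00000018916, chromosome 11, 54247271 to 54249667), Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683), Tnfrsf9 (ENSMUSG00000028965, chromosome 4, 150914562 to 150946102) and Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795).

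**Figure D2:**
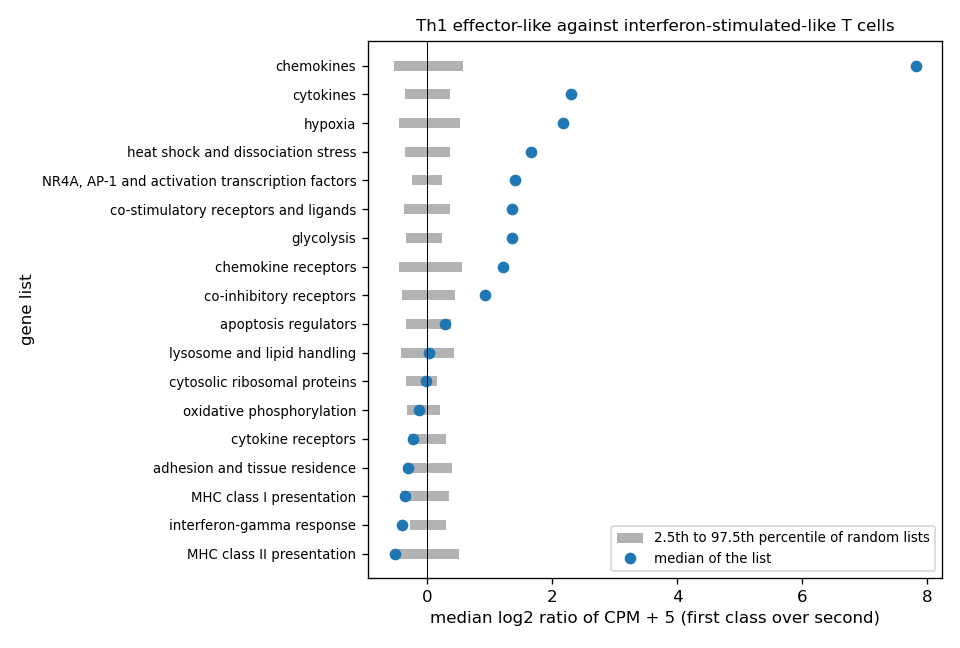
Median log2 ratio (CPM + 5) of each gene list, Th1 effector-like over interferon-stimulated-like cells of Smarta CD4 replicate 2; points are list medians and grey bars the central 95% of 10000 random lists matched on expression. Chemokines at 7.82 and cytokines at 2.30 lie farthest above the bars.

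The other named T cell classes were set against all remaining T cells. In interferon-stimulated-like cells, 15 list members were higher and 15 lower. Higher genes included the interferon response genes Irgm1 3.29-fold (2.84 to 3.79) and Gbp2 2.51-fold (2.12 to 2.94), the transcriptional regulator Id3 3.51-fold (2.97 to 4.13), Ctss 3.63-fold (3.08 to 4.25) and the co-stimulatory receptor Cd27 2.10-fold (1.77 to 2.46). Lower genes included Il2 383-fold (106 to 3163), Ccl3 124-fold (42.4 to 601), Tnfrsf9 3.90-fold (3.10 to 4.98), Lgals3 2.53-fold (2.27 to 2.83) and Hsp90aa1 2.89-fold (2.59 to 3.23). The higher count was 9 with doublets kept, 6 at resolution 2, 8 with thinned cells and 4 without cells carrying both tags. Proliferating-like cells had 0 list members higher and 19 lower, among them Ctla4 4.87-fold (4.41 to 5.39), Tnfrsf4 4.64-fold (4.36 to 4.94), Csf2 37.2-fold (31.3 to 44.6), Rgs1 6.59-fold (5.81 to 7.50), Nr4a1 5.67-fold (5.09 to 6.33) and Hspa1b 6.62-fold (5.32 to 8.32). With thinned cells these counts were 1 and 35. The remaining T cells include the cytokine-rich cluster in both contrasts.

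Free RNA in Smarta CD4 replicate 2 was read from 371468 barcodes outside the cell list with 100 UMIs or fewer, which held 4706001 UMIs. Cd3e was at 465 CPM there against 653 CPM in cells, Ifng at 1155 against 1855 and Il2 at 178 against 611. Across 5454 genes, which are not independent replicates, log CPM outside and inside cells correlated with Pearson's r of 0.971. Ifng rose to 2707 CPM and Il2 to 330.5 CPM at a limit of 50 UMIs. After thinning each cell to 2000 UMIs, 29.7% (27.0 to 32.5) of Th1 effector-like cells had an Il2 UMI against 0.537% (0.397 to 0.712) of other T cells. Unthinned shares were 34.8% and 1.61%, at median depths of 9012 and 6794 UMIs, and thinning left out 36 and 517 shallower cells. For Ifng the thinned shares were 69.7% and 8.63%. Unlike Il2, Ifng is a marker of the list that names this class and was not left out of the clustering features. The thinned counts also include UMIs used for clustering, so the Ifng difference is in part built into the class.

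CD11b replicate 1, with 10258 filtered cells, held several myeloid classes. Monocyte-like cells numbered 1230, an interval of 11.4 to 12.6%, cDC2-like cells were 10.8% (10.2 to 11.5), interferon-stimulated-like cells 9.36% (8.80 to 9.94) and patrolling monocyte-like cells 8.37% (7.84 to 8.93). Macrophage-like cells, led by Ccl24, Slc7a2, Nos2, Arg1 and Mmp12, made up 7.72% (7.21 to 8.25). Proliferating-like cells were 6.95% (6.47 to 7.46), neutrophil-like cells 6.83% (6.35 to 7.34) and mature dendritic cell-like cells 2.19%. T cell-like cells numbered 49, 0.478% (0.354 to 0.631), outside the intended sort. Unnamed clusters held 35.3% (34.3 to 36.2), among them cluster 2 led by Apoe and Ms4a7 (10.1%), cluster 3 led by G0s2 and S100a9 (10.5%) and cluster 10 led by the basophil genes Mcpt8 and Prss34 (2.00%). The sort for CD11b bounds these shares, and no test was possible with 1 library. The macrophage-like share was 2.99% at resolution 2 and no cluster took that name at resolution 0.5. Across settings monocyte-like cells ranged over 5.53 to 17.9%, neutrophil-like over 3.28 to 21.7%, patrolling monocyte-like over 2.02 to 14.7%, interferon-stimulated-like over 8.28 to 20.4%, proliferating-like over 4.81 to 14.3%, cDC2-like over 7.33 to 13.9% and mature dendritic cell-like over 2.17 to 4.39%.

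Within the CD11b cells, antigen presentation, interferon-gamma response, glycolysis and hypoxia genes were higher in the 792 macrophage-like cells than in the 1230 monocyte-like cells, classes that carried mostly different sample tags. This macrophage-like class was cluster 8 alone, and the unnamed cluster 2 led by Apoe and Ms4a7 (1037 cells) was outside the contrast. A C1qa-led macrophage-like cluster, cluster 0 of the library labelled Smarta CD4 replicate 1, was also set against monocyte-like cells. It had fewer genes higher: 2 of 14 for glycolysis, 3 of 10 for hypoxia and 7 of 20 for interferon-gamma response. For MHC class II presentation it had 8 of 10 higher. Of 10 MHC class II presentation genes 8 were higher, with H2-Eb1 26.1-fold (23.2 to 29.5), H2-Ab1 25.9-fold (23.5 to 28.6) and H2-Aa 23.8-fold (21.6 to 26.2). H2-Ab1 was at 4300.4 against 166 CPM. Of 20 interferon-gamma response genes 17 were higher, led by Nos2, the inducible nitric oxide synthase, at 475 against 4.37 CPM, 109-fold higher (95% interval 60.6 to 219). Iigp1 was 27.0-fold (18.8 to 40.4) higher and Cd274, which encodes PD-L1, 17.3-fold (13.6 to 22.3). Arg1, the arginase of alternatively activated macrophages, was 86.3-fold (64.6 to 118) higher at 1576 against 18.3 CPM.

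Chemokines were higher for 9 of 17, with the Cxcr3 ligand Cxcl9 225-fold (87.4 to 826), the eosinophil attractant Ccl24 158-fold (76.2 to 393) and Ccl8 114-fold (31.3 to 950.1). Glycolysis genes were higher for 13 of 14, with Tpi1 5.53-fold (4.98 to 6.14), Pfkl 4.25-fold (3.35 to 5.44) and Slc2a1 3.80-fold (3.23 to 4.49). Hypoxia genes were higher for 8 of 10, with the oxygen sensor Egln3 at 67.0 against 5.56 CPM, Ankrd37 7.93-fold (5.30 to 12.3) and Bnip3 7.43-fold (5.98 to 9.34). Of 12 immunosuppressive myeloid genes 6 were higher and 2 lower. Pdcd1lg2 and Retnla had 1 UMI each in monocyte-like cells against 142 and 71.5 CPM in macrophage-like cells. MHC class I presentation genes were higher for 5 of 9, with H2-Q7 17.9-fold (13.8 to 23.5), which shares sequence with other H2-Q genes, Tap2 3.76-fold (3.21 to 4.43) and H2-K1 2.86-fold (2.73 to 2.99). The interleukin 1 genes Il1a and Il1b were 48.3-fold (16.2 to 237) and 3.88-fold (3.61 to 4.17) higher, and the survival gene Bcl2a1b, a member of a near-identical family, 33.0-fold (25.9 to 42.9). Lpl was 5.87-fold (4.36 to 8.04) higher, Ctsl 2.55-fold (2.25 to 2.90), Egr2 8.21-fold (4.87 to 14.8) and Ccrl2 7.93-fold (6.69 to 9.47).

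Lower genes were fewer. Cd244a was 6.93-fold (4.83 to 10.2) lower in the macrophage-like cells, Id3 5.46-fold (3.77 to 8.11), Il6ra 2.89-fold (2.43 to 3.46), Itgb7 2.56-fold (2.22 to 2.96), Il15 2.49-fold (1.80 to 3.50) and Ndufa4 2.12-fold (1.92 to 2.34). Hspa1a and Hspa1b were 3.02-fold (2.75 to 3.32) and 2.66-fold (2.40 to 2.95) lower, while Ier3 of the same stress list was 3.55-fold (3.34 to 3.78) higher. In all, 83 of 259 list members were higher and 15 lower by the fixed rule, and the lower count was 8 at resolution 2. No test was possible with 1 library.

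The macrophage-like and monocyte-like classes also differed in sample tag. The tag mHTO02 marked 94.3% of singly tagged macrophage-like cells against 5.13% of singly tagged monocyte-like cells. Among cells with mHTO02 alone, 731 against 59, 48 list members were higher and 9 lower. There the log2 ratio of Nos2 was 2.53 in place of 6.77, of Arg1 4.44 in place of 6.43, of Cxcl9 4.12 in place of 7.81, of H2-Ab1 2.40 in place of 4.70 and of Cd274 1.04 in place of 4.11. Genes that no longer met the rule included Iigp1 at 0.57, Id3 at -0.63, Il15 at -0.14, Cd244a at -1.26, H2-K1 at 0.71, Pfkl at 1.20, Egln3 at 2.67, Lpl at 1.22, Ctsl at 0.51 and Egr2 at 1.29. Of these, Cd244a, Pfkl, Egln3, Lpl and Egr2 kept a ratio over 2 and missed the rule's level or interval condition. The monocyte-like side held 93214 UMIs there against 2519091 in the main contrast, so some losses may reflect fewer counts. Retnla was at -2.21 there, on the other side of 0 and short of the rule. The contrast with mHTO01 alone, 44 macrophage-like against 1090 monocyte-like cells, was not run, as 44 is under the least number set for a class.

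For 11 lists the median lay above the range of random lists: 2.69 for chemokines, 2.46 for immunosuppressive myeloid genes, 2.31 for hypoxia, 2.23 for MHC class II, 1.42 for glycolysis, 1.38 for co-stimulation (3 expressed members, 0 of 10 meeting the rule), 1.30 for interferon-gamma response, 0.84 for lysosome and lipid handling, 0.62 for cytokines 0.58 for apoptosis regulators, and for MHC class I at percentile 99.9. Ribosomal proteins at -0.38 and adhesion genes at -0.39 lay below it, and 0 lists did at resolution 2 or with the test lists left in. Within it were chemokine receptors at 0.21, cytokine receptors at 0.15, oxidative phosphorylation at 0.08, heat shock at 0.01, co-inhibitory receptors at -0.02 and NR4A and AP-1 at -0.10. The leading genes are Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419) and Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079).

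**Figure D3:**
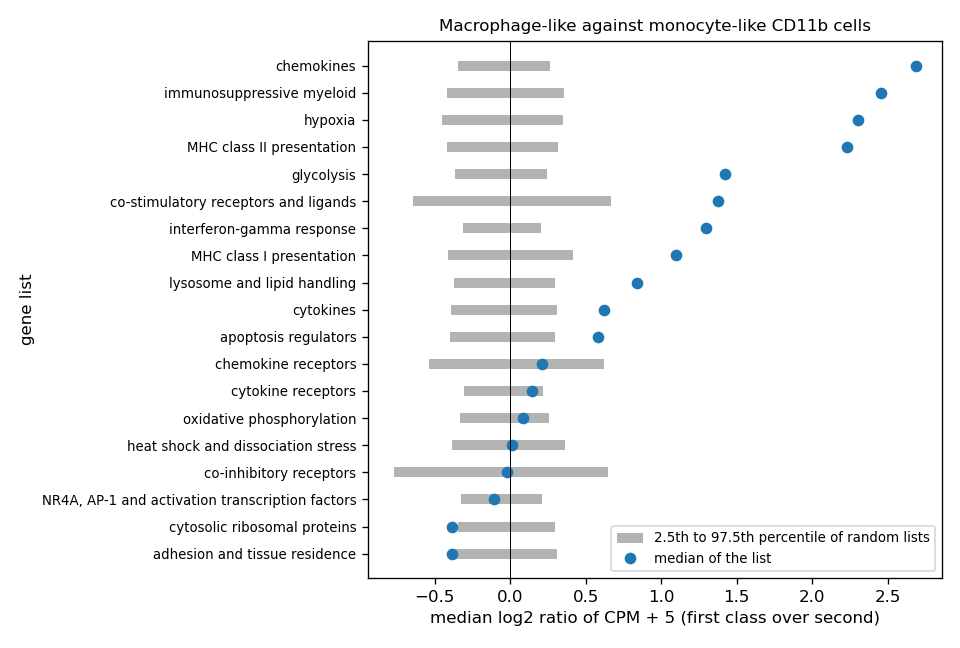
Median log2 ratio (CPM + 5) of each gene list, macrophage-like over monocyte-like cells of CD11b replicate 1; points are list medians and grey bars the central 95% of 10000 random lists matched on expression. Of the 19 lists 11 lie above their bars, from chemokines at 2.69 down to apoptosis regulators at 0.58.

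Between the groups, the 10569 T cells of Smarta CD4 replicate 2 were set against 10188 cells of CD11b replicate 1. Co-stimulatory receptors and ligands were higher in the T cells for 7 of 10, with 0 lower. Co-inhibitory receptors had 3 of 10 higher and 2 lower, and cytokine receptors 7 of 20 higher and 10 lower. Among the higher genes, Cd40lg was at 161 against 0.0372 CPM, Icos at 239 against 0.0931 CPM, Tigit at 153 against 0.0559 CPM and Il2rb at 469 against 0.149 CPM. Cd27 had 0 UMIs in the CD11b cells and was 1119.7-fold higher in the T cells, against a floor of 3 UMIs. All 10 MHC class II presentation genes were lower in T cells, with H2-Aa at 0.851 against 2440.3 CPM, and so were 16 of 20 interferon-gamma response genes and 11 of 17 chemokines. Cxcl2 was at 0.0431 against 3317 CPM, Il1b at 0.0646 against 1643 CPM, Csf2rb, a GM-CSF receptor chain, at 0.129 against 315 CPM and Hspa1a at 46.4 against 710.2 CPM. Thbs1, a matricellular glycoprotein gene, had 0 UMIs in T cells and was 29171-fold lower with the same floor of 3 UMIs. Glycolysis had 1 of 14 genes higher in T cells, Ldha at 2.52-fold (2.49 to 2.54), and 3 lower. Oxidative phosphorylation had 1 of 16 higher, Atp5b at 2.60-fold (2.56 to 2.64), and 0 lower. Ribosomal proteins had 4 of 16 higher, among them Rps2 at 2.66-fold (2.64 to 2.68), and 0 lower. Of 259 list members 38 were higher and 96 lower, and this compares 2 libraries of different sorts, not replicated conditions. With groups taken as labelled and Smarta CD4 replicate 2 left out, 3 were higher and 2 lower. Scaling by DESeq2 size factors shifts every log2 ratio by -0.25.

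With the groups as labelled, the 2 libraries labelled Smarta CD4 against CD11b replicate 1, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14833 genes. At an unadjusted p under 0.05 it gave 1 gene. DESeq2's Wald test called 7 genes, all higher in the labelled Smarta group, with 344 below that unadjusted level. The common dispersion was 1.14, at which 0 of 200 simulated 8-fold changes were recovered, and the lone CD11b library was assumed to vary like the labelled group. Tumor against lymph node T cells, and vehicle against Smarta-treated CD11b cells, were not compared, because no source used here states which tissue or treatment a sample tag marks. The tags of the T cell-like cells in CD11b replicate 1, given under other observations, bear on treatment only indirectly.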

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

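Of the tests below, those on mixed-in myeloid cells, on a second deposit of CD11b replicate 2 (its wording), on pairs of cells in a droplet and on free neutrophil RNA were chosen only after the result was seen.

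The library labelled Smarta CD4 replicate 1 gave a signal outside the T cell class comparisons: Lyz2 at 5514 CPM with Cd3e at 0.0189 CPM. T cells with myeloid cells mixed in would need T cell transcripts, yet the upper bound of Cd3e was 0.0163% of the level in Smarta CD4 replicate 2. Of its 6621 barcodes, 141 were in the CD11b replicate 2 list, within the 135 to 184 that random draws gave, and 91 were in the CD11b replicate 1 list (chance 90 to 131), which argues only against either library having been deposited a second time under this name. An exchange of files with CD11b replicate 2 would leave the same overlap, so it stays open with a wrong label or an exchange outside the series, any of which may account for the pattern. No biological explanation was tested.

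In CD11b replicate 1 an unnamed cluster of 1073 cells combined neutrophil transcripts (S100a8 at 9209.9 CPM, Cxcr2 at 225) with C1qa at 212 and Arg1 at 607 CPM, at a median of 6380 UMIs against 1747 in neutrophil-like cells; a similar cluster of 351 cells in the library labelled Smarta CD4 replicate 1 had C1qa at only 24.1 CPM, 2.15 times the cDC2-like level against 25.7 times here. Free neutrophil RNA alone would reach all types alike, but the smaller of the S100a8 and S100a9 ratios to cDC2-like cells was 53.4. Both tags were carried by 10.3% of its cells (upper bound 12.3), against 33.4% in simulated pairs with a random partner and 4.86% with a macrophage-like partner, a variant added after the first had been read; in the other library the share was 9.40% against 42.7% with a random partner. Pairs of cells in a droplet cannot be told apart from single cells here, because the expected share depends on the partner assumed. Engulfed neutrophils were not tested, and no group of the design bears on them.

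The Il2, Il3 and Csf2 transcripts of the Th1 effector-like cells were weighed against depth, free RNA and handling. With each cell thinned to 2000 UMIs, 45.8% of these cells and 2.72% of other T cells had a UMI of any of the 3, which argues against depth. The smallest of their ratios to barcodes outside the cell list was 12.8, against free RNA. Hspa1a was 11.7, Hspa1b 11.7, Fos 4.07 and Jun 5.63 times the level in other T cells, as stress during tissue dissociation would give, so it stays open; against interferon-stimulated-like cells with mHTO02 alone, Hspa1a and Hspa1b were at log2 ratios of 0.99 and 0.75, short of the rule, Cd69 at -0.04, Il2 at 8.27 and Csf2 at 6.60. T cell activation in tumor or lymph node, which also raises these genes, is a biological alternative that the pooled design leaves untested.

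A further signal lies in the sample tags, which no planned comparison uses: mHTO02 was the tag of 98.9% of singly tagged Th1 effector-like cells, against 29.5% of all singly tagged cells of that library. In CD11b replicate 1 it was the tag of 94.3% of singly tagged macrophage-like cells against 44.3% of all singly tagged cells. This does not hold for all cells with macrophage genes. In the unnamed cluster 2 of that library, led by Apoe and Ms4a7, mHTO02 was the tag of 2.60% (24 against 899 with mHTO01). In the library labelled Smarta CD4 replicate 1 it was the tag of 29.1% of singly tagged macrophage-like cells. CD11b replicate 1 also held 49 T cell-like cells, led by Ifng, Trbv13-1 and Il2, in a sort for CD11b.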

How the results depend on the processing

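Settings that leave out cells with both tags, change the naming conditions, compare with all other T cells, keep cells of 1 tag alone, or apply doublet, depth, feature or list checks beyond those first listed were chosen after seeing the data. No named gene reversed past the rule: of 252 values for the Th1 effector-like contrast 245 kept their direction and 222 met the rule; of 322 for macrophage-like cells 321 and 272; of 319 for other T cell classes 319 and 277; and of 106 between the groups 106 and 105. Part of this agreement was fixed in advance. Size factors move every log2 ratio between the groups by the same -0.25, which cannot reverse a gene that met the rule. With doublets kept the macrophage-like contrast is the main one, since 0 cells were marked there. The setting with all UMIs includes the UMIs of the main setting. Of 72 other class shares 37 stayed within the counting interval. List members higher ranged from 48 to 67 in the Th1 effector-like contrast and from 48 to 83 in macrophage-like cells. Class shares moved with most settings. With at least 200 genes and under 20% mitochondrial UMIs, the Th1 effector-like share was 9.66%, interferon-stimulated-like 5.04% and macrophage-like 7.15%. With doublets kept the interferon-stimulated-like share was 5.17%. At resolution 0.5 monocyte-like cells were 16.0%. At resolution 2 interferon-stimulated-like, macrophage-like and monocyte-like shares were 2.77, 2.99 and 7.91%, with test lists left in 3.72, 8.57 and 17.9%, and with thinned cells 6.35, 11.1 and 5.53%. Without cells carrying both tags interferon-stimulated-like cells were 12.7%. No cluster was Th1 effector-like at resolutions 0.5 and 2, with test lists left in or thinned, so these gave no gene comparison; the same held for interferon-stimulated-like and macrophage-like at 0.5 and monocyte-like without both-tag cells. A memory or stem-like class appeared in 4 settings, at 5.75 to 27.4%. Without the both-tags condition proliferating-like T cells were 26.3% and neutrophil-like cells 17.3%.

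With at least 200 genes and without both-tag cells the Th1 effector-like contrast was made against a memory or stem-like class, and elsewhere against interferon-stimulated-like cells. Lower list members in that contrast were 5 without both-tag cells, 4 of them shared with the main 10, and 2 against all other T cells; in macrophage-like cells they were 8 at resolution 2, 7 shared, and with mHTO02 alone 48 were higher and 9 lower, 42 and 8 shared. Lists below the random range in the Th1 effector-like contrast numbered 0 with doublets kept, 1 with all UMIs and 0 against all other T cells, against 2; in macrophage-like cells 0 at resolution 2 and 0 with test lists left in. Higher members in interferon-stimulated-like cells were 9 with doublets kept, 6 at resolution 2, 8 thinned and 4 without both-tag cells, against 15. In proliferating-like cells thinning gave 1 higher and 35 lower, against 0 and 19. Between the groups, leaving out each labelled Smarta replicate gave from 3 to 38 members higher and from 2 to 99 lower, the low counts from the library labelled Smarta CD4 replicate 1 alone. With groups as labelled DESeq2 called 7 genes and edgeR 0. Free RNA at a limit of 50 UMIs gave Cd3e 521, Ifng 2707 and Il2 330.5 CPM. The cause was not tested for any of these. No paired analysis was possible because only 1 of the libraries labelled Smarta CD4 holds T cells and CD11b counts came from 1 library. For the same reason the replicate-block, size-factor, low-count-filter, DESeq2, camera and fry alternatives of the T cell classes, scaling over all cells together, and leaving out each replicate there were not run; nor were the alternatives of the tissue and treatment contrasts, for want of a tag map.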

Other observations

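The test of the tags was chosen only after the result was seen, as were the clusters described here.

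The library labelled Smarta CD4 replicate 1 held myeloid classes. Macrophage-like cells made up 15.3% (14.5 to 16.2), cDC2-like cells 13.4% (12.5 to 14.2), interferon-stimulated-like cells 12.1% (11.3 to 12.9), neutrophil-like cells 11.1% (10.4 to 11.9) and monocyte-like cells 9.69% (8.97 to 10.4). Across settings these ranged over 2.29 to 15.3%, 12.4 to 14.9%, 7.46 to 26.8%, 5.52 to 16.7% and 9.69 to 13.5%, and patrolling monocyte-like cells over 1.71 to 13.5%. Proliferating-like cells were 5.46%, patrolling monocyte-like 3.10%, mast cell or basophil-like 2.64%, mature dendritic cell-like 1.73% and unnamed clusters 25.5%. Macrophage-like cells comprised a pair of clusters. Cluster 17, with 260 cells, was led by Nos2, Ccl24 and Slc7a2, and cluster 0, with 704 cells, by the complement genes C1qa, C1qc and C1qb.

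Against monocyte-like cells of the same library, cluster 17 had 90 list members higher and 15 lower. Arg1 was 354-fold (138 to 1303) higher, Iigp1 121-fold (60.9 to 282), Cd274 43.4-fold (31.1 to 62.5), the oxygen sensor Egln3 59.6-fold (19.7 to 295) and Bnip3 20.8-fold (14.4 to 31.2). All 14 glycolysis genes measured were higher, with Tpi1 8.46-fold (7.28 to 9.86), and H2-Ab1 was 13.3-fold (12.2 to 14.6) higher. Nos2, at 454 CPM, had 0 UMIs in monocyte-like cells and was at least 332-fold higher. Cluster 0 had 51 members higher and 2 lower. There Ccl12 was 47.3-fold (23.9 to 109.9) higher, Cxcl16 32.1-fold (17.9 to 64.5), Rgs1 19.7-fold (15.9 to 24.9), Vegfa 11.3-fold (8.08 to 16.1) and Il1b 4.28-fold (4.06 to 4.52), while 2 of 14 glycolysis genes were higher by the rule. The glycolysis list's median log2 ratio in cluster 0 was still 0.62, at percentile 99.98 of random lists. Singly tagged cells of cluster 17 all carried mHTO02 and monocyte-like cells almost only mHTO01, so class and tag cannot be separated in its contrast. Id3 was 14.4-fold (7.17 to 33.6) lower in cluster 17, as was Hspa1a 5.33-fold (4.64 to 6.14).

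Many classes lay mostly with a single tag while others were shared, and no source used here says what each tag marks. All shares in this paragraph are of singly tagged cells. Shared classes had these mHTO02 shares in the library labelled Smarta CD4 replicate 1 and in CD11b replicate 1. They were 22.7 and 24.9% for cDC2-like, 64.9 and 66.5% for patrolling monocyte-like, and 77.8 and 60.1% for mature dendritic cell-like cells. In the library labelled Smarta CD4 replicate 1, mHTO02 marked 33.6% of all such cells, 255 of 255 in cluster 17 and 2.23% in cluster 0. It marked 1% of monocyte-like, 87.5% of neutrophil-like and 2.00% of interferon-stimulated-like cells there. In CD11b replicate 1 it marked 5.13% of monocyte-like, 663 against 17 of neutrophil-like, 1.08% of interferon-stimulated-like and 95.2% of proliferating-like cells. Of the 49 T cell-like cells there, 39 carried mHTO02 and 7 mHTO01, which is 84.8% (71.1 to 93.7) mHTO02 against 44.3% of all cells. Rag1-deficient mice make no T cells of their own, so mHTO02 may mark mice given Smarta cells in that library. This was not tested, and the 7 cells with mHTO01 go the other way. In Smarta CD4 replicate 2 it marked 11.1% of proliferating-like, 21.7% of interferon-stimulated-like and 94.2% of cluster 4 cells, led by Ccl5, Fos and Klrg1.

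A hypothesis is that each tag may mark the same kind of sample in both myeloid libraries. Across 4985 genes, which are not independent replicates, the log2 ratio of mHTO02 to mHTO01 cells correlated between them with Pearson's r of 0.892 and Spearman's rho of 0.835. Between the T cell library and CD11b replicate 1 it was 0.250 over 3962 genes. Monocyte-like, neutrophil-like and interferon-stimulated-like cells lean to the same tag in both myeloid libraries. The correlation between these libraries in part restates those shares and is not independent of them. The test does not say which treatment or tissue a tag stands for.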
